A study of Mus musculus with 23 samples.

How the data were processed

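Methylation was measured by AIMS-seq in 23 mouse libraries of 9 groups. The genomic intervals between consecutive SmaI/XmaI sites serve as fragments, and reads come from fragments whose site at each end is methylated. Libraries were sequenced on an Illumina GA2 and aligned to mm9, per the labels' protocols. The submitters' processing notes name Bowtie 0.11.3 and DESeq (without a version), and state no read filter. The deposited count table holds raw read counts per fragment and library, per the file headers and the whole numbers in it. The authors also deposited a scaled table with a depth-corrected score per fragment, which is each raw count times a single factor per library, to within 1. The scaled values of fragments under 2000 bp sum to 5911718 to 5914756 per library. The authors' comparison tables give p-values and adjusted p-values from DESeq with pooled and with per condition dispersion, per the file headers. Their log2 values, as deposited, are log2 of the ratio of mean scaled values after adding 1 to each mean, which was recomputed and was equal. These tables hold fragments from 21 bp to under 2000 bp and count the 4 ESC libraries separately. The 161 further columns deposited per sample were equal to the scaled table and were not used.

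Fragment starts and ends were checked against the mm9 sequence, and 100% of them lie at a CCCGGG site. Genes came from GENCODE M1 on mm9. A fragment was given to a gene if it overlaps the gene body or the 2000 bp upstream of it, which gave 103418 fragments a gene, and it was called promoter if it overlaps the window from 2000 bp upstream to 500 bp downstream of a start. This assignment was chosen once the tables could be read and before any test. CpG island, shore and repeat classes are those of the deposited tables. A fragment can hold several genes, and the gene named is a listed one.

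Raw counts were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM scaling, filterByExpr with a minimum count of 10, 2-sided, Benjamini-Hochberg adjustment over all fragments tested, threshold 0.05) on the libraries of the 2 groups compared. The CGR8 library and its technical replicate were summed, so ESC has n = 3 lines. There were 9 comparisons. Lists of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated as an alternative and with fry, for lists with 5 or more tested fragments and with adjustment over the lists of a comparison. A fry p asks whether a list's fragments move, on balance, one way, and does not compare the list with other fragments. The 14 lists are pluripotency, myogenic regulators, contractile genes, germ line, HOX, imprinted genes, protocadherin clusters, neural, endoderm, blood, endothelial, fibroblast, adipocyte and Schwann cell genes. Genomic contexts were compared with Fisher's exact test against all fragments tested. Shares of reads and numbers of fragments with 5 or more reads were compared with exact permutation tests, after libraries were thinned to 1 depth for the latter. The work ran in R 4.3.3 with data.table (1.17.8) and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

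The groups, comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule takes (a) the tested fragment with the smallest p of 14 genes fixed in advance, whatever its result, (b) per list up to 4 called fragments with the smallest adjusted p in each direction, (c) the 8 largest folds in each direction among called fragments of a named gene whose libraries do not overlap and whose mean is at or above the median, and (d) the 4 smallest adjusted p in each direction. Of the 14 genes, those without a value had no tested fragment. The fragment of a gene was picked anew for each comparison. The names Dppa4, Pax3 and Pax7 therefore stand for different fragments in different comparisons. The rule gave more fragments than a text can name, and a first hand-made choice among them leaned to higher fragments. It was replaced by a fixed narrowing, itself set after values had been seen, which keeps all of (a), the smallest adjusted p per list and direction among fragments under 2000 bp, and the first of (c) and (d) per direction. It named 31 of 98 for myoblasts against ESC, 17 of 66 for day 4 myotubes against ESC, 29 of 121 for muscle against ESC and 29 of 103 for muscle against myoblasts. For myoblasts against ESC, 1 of these is left out of the text, and counts of named calls include it. The genomic contexts given in the text were also chosen after values had been seen.

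Where a group had 0 reads, a fold is a bound against 3 reads over that group. Where it had 1 to 3 reads, the ratio is given with an exact (Clopper-Pearson) 95% interval. PCR reads here carry no molecular identifiers, so intervals and floors cover counting error only. Alternatives set in advance were DESeq2's size factors, library totals, no low-count filter, DESeq2, all groups in one fit, the 4 ESC libraries kept apart, the culture as a replicate block, and each library left out. Fragments under 2000 bp, autosomes, fragments outside CpG islands and the second CGR8 library alone were added after the data were seen. With a library left out, edgeR pooled the spread over groups, and the lone passage 0 library was taken to vary like the myoblasts. The culture numbers in the titles pair myoblasts, myotubes and passage 0 cells. The replicate numbers follow them for myoblasts and myotubes but not for passage 0. Deviations from the group means correlated between libraries of the same culture, at 0.88, 0.63 and 0.62 for day 1 in cultures 21, 27 and 26, at 0.75, 0.47 and 0.74 for day 2, at 0.62 to 0.85 for day 4 and at 0.27 for passage 0.

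The pipeline was tested on simulated data with the means and spread of 4 comparisons and no pairing by culture. Of 100 fragments changed 16-fold it recovered 93 for myoblasts against ESC, 99 for muscle against ESC, 84 for muscle against myoblasts and 0 for day 4 myotubes against myoblasts. Of 100 changed 4-fold it recovered 6, 24, 2 and 0. With so few changed fragments the adjusted threshold is stricter than in comparisons with many calls, so these shares do not measure power there. Of the calls in the first 3 comparisons, 7.48%, 8.21% and 8.51% were unchanged fragments, each above the share that the threshold of 0.05 stands for. The simulated day 4 comparison gave no calls, so it has no such share. In the simulated muscle against ESC data, a set of 40 fragments raised 4-fold was found by camera and 3 of 200 random sets were at p under 0.05. Simulated fragments were drawn independently, so this says nothing on lists whose fragments move together. Groups of 1 library each, the never cultured cells, were left out of all tests and are described as values.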

Results

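The libraries were made by AIMS-seq, which reads DNA methylation through a pair of restriction enzymes that share the site CCCGGG. SmaI cuts the site where it is unmethylated and leaves blunt ends. XmaI then cuts the sites that stayed methylated and leaves cohesive ends, and adaptors join only these, so amplified fragments lie between neighbouring methylated sites. More reads of a fragment thus stand for more molecules with methylation at both of its ends, and a read count is not a percentage of methylation. The 23 libraries fall into 9 groups. Mouse embryonic stem cells (ESC) gave 4 libraries from 3 lines (CGR8 with a technical replicate, RD1 and E14Tg2, all of 129 backgrounds). Myoblasts were grown from C57BL/6J muscle as cultures 21, 27 and 26, were sampled at passage 8 to 10, and were sampled again as myotubes after 1, 2 and 4 days of differentiation, with 3 libraries per stage. Skeletal muscle tissue gave 3 libraries, of which 1 is C57BL/6J and the other two are of mixed 129Sv/C57BL/6J background. Passage 0 cells of cultures 26 and 27 gave 2 libraries, and muscle precursor cells that were never cultured gave 1 library from uninjured muscle and 1 from muscle 3 days after cardiotoxin injury. Strain and cell type change together between ESC and the cultures.

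The deposited table gives whole read counts for 173430 fragments of the mm9 genome, one for each interval between consecutive sites, with a median length of 6711 bp. Libraries held from 6237851 to 14696855 reads, and 92.4% of all reads came from fragments of 200 bp or more and under 2000 bp. PCR hardly amplifies fragments of 10000 bp or longer, so reads of such fragments named below may not stand for methylation at both ends. Where those reads come from was not tested. No library had a read in 21542 fragments. Of all fragments, 49191 touch a promoter, 25356 an exon outside promoters, 24816 an intron and 74067 lie between genes, while 28212 overlap a CpG island. With every library thinned to the depth of the smallest one among the groups tested, 5 or more reads were found in 32826 ± 2295 fragments of ESC, 27349 ± 2217 of myoblasts, 24820 ± 4501 of day 4 myotubes and 20045 ± 1852 of muscle (mean ± SD, n = 3). The exact permutation p of muscle against ESC and of myoblasts against ESC was 0.1, 2-sided, the smallest that 3 against 3 libraries can give. Fragments of 2000 bp or longer made up 51.5 ± 5.13% of the detected ones in ESC and 40.4 ± 4.00% in myoblasts. They made up 33.7 ± 3.04% in day 4 myotubes and 21.9 ± 4.03% in muscle. The lower numbers thus go with fewer long fragments and do not show a fall among shorter ones. CPM stands for counts scaled to library size. Below, levels given as mean ± SD with n = 3 per group are CPM after TMM scaling within each comparison. The same libraries can thus have different levels in different comparisons. Plotted levels, reads of promoter islands and sex chromosomes, and levels in the section on never cultured cells are CPM of all reads, without TMM scaling. Fold changes are log2 ± SE from edgeR's quasi-likelihood test, and a fragment was called at a Benjamini-Hochberg adjusted p under 0.05.

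Myoblasts were compared with ESC, that is, muscle precursors with pluripotent cells. The Dppa4 promoter (a nuclear factor of pluripotent cells; mm9 chromosome 16, 48284242 to 48284769, 528 bp, overlapping a SINE) stood at 247 ± 61.4 CPM in myoblasts and 1.29 ± 0.793 in ESC, higher by 7.54 ± 0.71 on the log2 scale (edgeR adjusted p = 0.000146). An intron fragment of Cdh1, which encodes E-cadherin of epithelia (chromosome 8, 109157668 to 109158644), had 1390 reads in myoblasts and 3 in ESC, a ratio of 755 with an exact binomial 95% interval from 258 to 3665.5 (edgeR adjusted p = 0.00014). In the other direction, the Myf5 exon fragment (a myogenic transcription factor; chromosome 10, 106921116 to 106921344) fell from 52.7 ± 13.1 CPM in ESC to 5.40 ± 3.83 in myoblasts, a log2 change of -3.28 ± 0.72 (edgeR adjusted p = 0.0102). In total 2068 fragments were higher and 2937 lower in myoblasts, of 25152 tested.

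Among myogenic regulators, 3 of 39 tested fragments were higher in myoblasts and 3 lower, and 0 and 3 when adjusted over the list alone. An exon fragment of Pax7, the paired-box factor of muscle stem cells (chromosome 4, 139294972 to 139295493), rose from 37.6 ± 12.7 to 137 ± 76.8 CPM. The promoter shore of Mef2c, a muscle transcription factor, rose by 1.79 on the log2 scale, and an island exon fragment of Cdh15, the M-cadherin of muscle cells, changed by -5.09. The Pax3 promoter island (chromosome 1, 78193784 to 78194508) did not pass at 1.98 (edgeR adjusted p = 0.0985; DESeq2 adjusted p = 0.0211), nor did the promoter of Acta1, skeletal muscle actin (chromosome 8, 126417989 to 126418689), at -1.62 (edgeR adjusted p = 0.16). Of the contractile list, 4 of 67 fragments were higher and 7 lower, the same adjusted over the list alone. An exon of Ryr1, the calcium release channel of muscle (chromosome 7, 29889340 to 29889751), had 2889 reads in myoblasts and 4 in ESC.

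Pluripotency genes had 7 fragments higher and 3 lower of 23 (9 and 5 adjusted over the list alone), with an intron fragment of Jarid2, a partner of Polycomb complex PRC2, changed by -2.91. Adipocyte genes had 0 higher and 5 lower of 19 (0 and 7 adjusted over the list alone), among them an exon of Plin1, a coat protein of lipid droplets, at -2.45. HOX genes had 3 higher and 1 lower of 17, the same adjusted over the list alone, with Hoxc5 up by 5.30 (chromosome 15, 102846100 to 102846466; 322 ± 185 against 8.20 ± 4.56 CPM) and Hoxd4 changed by -2.01. Imprinted genes had 1 higher and 7 lower of 43, the same over the list alone, and the intron fragment of Trappc9, a vesicle tethering factor, changed by -2.85. Germ line genes had 1 and 4 of 29, with Piwil1, a PIWI protein of the male germ line, up by 5.76 and Dmrtb1, a transcription factor of spermatogenesis, changed by -2.56.

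Of genes of other lineages, neural genes had 4 fragments higher and 3 lower of 48, with the promoter of Lhx2, a forebrain factor (chromosome 2, 38205505 to 38206082), up by 3.21 and an intron of Rbfox3, the neuronal splicing factor NeuN, changed by -3.66. Endoderm genes had 5 and 4 of 24, and the exon fragment of Cdh1 (chromosome 8, 109173045 to 109174908) changed by -2.28 while the intron fragment of the same gene rose. Blood cell genes had 3 and 6 of 41, with an intron of Itgam, the myeloid integrin CD11b (chromosome 7, 135266476 to 135267121), at 110 ± 30.0 against 0.296 ± 0.347 CPM and the promoter of Runx3, a T cell transcription factor, changed by -2.95. Endothelial genes had 3 and 1 of 39, where Erg rose by 4.14 and Emcn changed by -1.73. Fibroblast genes had 3 and 3 of 39, where Osr1 rose by 2.66 and Alx4 changed by -3.42. The Schwann cell list had 0 and 1 of 7, the lower one in Pmp22, a protein of peripheral myelin, at -2.69. The camera test called none of the 13 lists with enough tested fragments (lowest adjusted p = 0.0921, for pluripotency and adipocyte genes). Fry called imprinted and endothelial genes as lower (fry adjusted p = 0.00641 and 0.0145) and pluripotency genes as higher (0.0145).

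The largest fold changes under the rule for named genes were at an intron of Micall1, at least 853-fold higher in myoblasts (1408 against 0 reads), and at a 16392 bp fragment at Cpt1c, a brain enzyme of the carnitine palmitoyltransferase family, at least 1115-fold lower (0 against 6477 reads). The limit of long fragments given above holds for Cpt1c. The smallest adjusted p values were those of Padi1 and Kcnh1 (edgeR adjusted p = 8.89e-05 for both). The promoter of Padi1, a protein deiminase, changed by 8.81. A 7449 bp intron fragment of the potassium channel gene Kcnh1 changed by -8.99. Both Cpt1c and Kcnh1 fragments are longer than 2000 bp, and strain and cell type change together in this comparison. By region, LINE elements held 588 of the 2068 higher fragments, or 28.4% (odds ratio 2.09 by Fisher's exact test), and promoters held fewer than their share (odds ratio 0.511). Fragments of 2000 bp or longer held 1587 of the 2937 lower ones (odds ratio 2.31). Without the filter the latter ratio was 0.354, and with DESeq2 that of promoters was 0.964. Without ESC line 3 the total fell to 3247 calls. Of the 29 named calls, 9 were lost without ESC line 1 (edgeR adjusted p from 0.0512 to 0.159), 5 without line 2 (0.0504 to 0.139), and 11 without line 3 (0.0505 to 0.18). A further 4 were lost without myoblast culture 27 (0.0524 to 0.097), 11 without culture 26 (0.0508 to 0.146) and Emcn without culture 21 (0.0554). The genes concerned included Myf5, Pax7, Jarid2, Mef2c, Cdh15, Dmrtb1, Hoxd4, Rbfox3, Cdh1 at its exon, Runx3, Emcn, Osr1 and Pmp22, while Pax3 passed without culture 21 (0.00473). With all groups in one fit 14 named calls were lost (edgeR adjusted p from 0.0535 to 0.206), among them Myf5 (0.136), Pax7 (0.116), Jarid2 (0.205), Plin1 (0.0993) and Alx4 (0.061). Library totals ended the calls of Pax7 (0.0551) and Mef2c (0.0841), the lack of a low-count filter those of Mef2c, Hoxd4 and Emcn (0.0655 to 0.114), and the 4 ESC libraries kept apart that of Alx4 (0.0708). Fragments under 2000 bp alone ended that of Mef2c (0.0505) and the second CGR8 library that of Hoxd4 (0.0523). With fragments under 2000 bp alone, 58.3% of the calls were higher instead of 41.3%, and the median of all log2 changes was -0.08 with the main scaling, 0.07 with DESeq2's size factors and -0.29 with library totals.

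Day 4 myotubes, the latest stage in culture, were compared with the same ESC lines. The Dppa4 promoter stood at 340 ± 210 CPM in myotubes, a log2 change of 8.18 ± 0.95 (edgeR adjusted p = 0.0018). The Mef2c promoter rose by 3.18, Ryr1 by 10.80, Hoxc5 by 5.13, Lhx2 by 3.64, Piwil1 by 5.40, the Itgam intron by 8.79 and the promoter of Eng, the endothelial receptor endoglin (chromosome 2, 32502467 to 32503075), by 3.64. The Cdh1 intron fragment had 1478 reads against 3, a ratio of 789 with an exact 95% interval from 269 to 3829.6. An intron of the kinase gene Map4k4 had 553 reads against 1, a ratio of 885 with an interval from 158 to 35036. A 7312 bp intron fragment of the potassium channel gene Kcnb2 had 2 against 3908, lower by a ratio of 1220.4 with an interval from 338 to 10080. A 9335 bp fragment at the promoter of Mgst2, a glutathione transferase, was at least 1637-fold lower (0 against 8414 reads). The Kcnb2 and Mgst2 fragments are longer than 2000 bp, and strain and cell type change together in this comparison. An 80375 bp fragment at Fbxo33 (chromosome 12, 60238187 to 60318561) had 71229 reads against 9. PCR hardly amplifies a fragment as long as that of Fbxo33, so its reads may not stand for methylation at its ends. Myf5 at -1.76, Pax3 at 3.17, a 296 bp Pax7 fragment at 3.63 and Acta1 at -1.19 did not pass (edgeR adjusted p = 0.331, 0.136, 0.103 and 0.507). Pax3 and Pax7 passed with DESeq2 (adjusted p = 0.012 and 0.00388) and in edgeR without the low-count filter (0.00383 and 0.000177).

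Camera called pluripotency genes, with 6 fragments higher and 1 lower of 26 in day 4 myotubes (9 and 1 adjusted over the list alone), and HOX genes, with 3 higher and 0 lower of 17 (camera adjusted p = 0.0475 for both). Neither list passed when its correlation was estimated (camera adjusted p = 0.9 with an estimated correlation for both). The calls were also lost with DESeq2's size factors (0.0504 for both) and with fry (0.0799 and 0.366), for HOX genes outside islands (0.0953), and without ESC line 1 (0.0836 for both), line 2 (0.121 and 0.0751), line 3 (0.0548 and 0.246) and day 4 library 2 (0.065 and 0.312). Fry called imprinted genes as lower (fry adjusted p = 0.01). In all, 1382 fragments were higher and 1511 lower of 25497 tested. Fragments of 2000 bp or longer made up 1377 of the lower ones, or 91.1% against 35.6% of those tested, and LINE elements held 325 of the higher ones (odds ratio 1.60) with CpG islands at 23 (odds ratio 0.441). Both turned under alternatives, islands to 5.83 with DESeq2 and 2.03 without the filter, and LINE elements to 0.827 without the filter. With fragments under 2000 bp alone, 948 were higher and 127 lower, and without day 4 library 1 the total was 6146. The Mef2c and Eng calls were lost without ESC line 2 (edgeR adjusted p = 0.0583 and 0.0878) and without line 3, where Lhx2 was lost too (0.083, 0.096 and 0.0686). Myf5 passed without day 4 library 2 (0.0297) and Pax3 and Pax7 without library 1 (0.00581 and 0.00546). The median log2 change of all tested fragments was 0.00 with the main scaling, 0.16 with DESeq2's size factors and -0.52 with library totals.

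Muscle tissue and ESC differed at 13575 of 22980 tested fragments (5616 higher and 7959 lower). Promoters of muscle genes went different ways. Those of Ckm, Pax3 and Pax7 had more reads in muscle, that of Acta1 did not pass, and that of Cacng1 was lower (-2.58). The promoter of Ckm, muscle creatine kinase (chromosome 7, 19996443 to 19997294), stood at 65.5 ± 15.6 CPM against 0.151 ± 0.193, a log2 change of 8.41 ± 0.78 (edgeR adjusted p = 2.83e-05). The Pax3 promoter island rose from 2.69 ± 1.41 to 161 ± 104 CPM and a promoter island of Pax7 (chromosome 4, 139388132 to 139388427) from 4.27 ± 1.96 to 205 ± 111. Dppa4 stood at 704 ± 263 CPM against 1.03 ± 0.626, a log2 change of 9.36 ± 0.70 (edgeR adjusted p = 1.07e-05). Myf5, at 44.2 ± 20.2 against 42.4 ± 9.81 CPM, and Acta1, at 209 ± 143 against 98.4 ± 24.2, did not pass (edgeR adjusted p = 0.908 and 0.0941). For Myf5 the direction depends on the scaling. As CPM of all reads it had 22.4 to 43.9 in the muscle libraries and 51.5 to 66.6 in the ESC libraries. With library totals its log2 change was -0.81, which did not pass either (edgeR adjusted p = 0.0795).

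HOX genes moved in one direction, with 13 fragments higher and 0 lower of 17 (the same adjusted over the list alone), led by the Hoxa2 promoter (chromosome 6, 52114462 to 52115046) at 170 ± 83.0 against 2.58 ± 1.28 CPM. Camera called the HOX list (adjusted p = 0.000205), the pluripotency list (0.00391; 14 higher and 6 lower of 24), the endoderm list (0.00391; 14 and 4 of 23) and the neural list (0.00524; 20 and 4 of 47). None of these kept its call once the correlation was estimated (camera adjusted p = 0.634, 0.634, 0.634 and 0.735 with an estimated correlation). The neural call was lost without muscle 2 (0.0697) and with fry (0.0734), and the neural median, 0.82 with the main scaling, was -0.05 with library totals. Beside these lists, reads from autosomal promoter islands numbered 24569, 32145 and 11011 CPM in muscle libraries 1, 2 and 3, and 5347 to 6333 in the 4 ESC libraries. Lhx2 rose by 5.10 and the Cdh1 intron fragment reached 799 reads against 3, a ratio of 639.6 with an exact 95% interval from 218 to 3108. The Rbfox3 promoter changed by -0.90 (edgeR adjusted p = 0.0372) and the Cdh1 exon fragment by -1.66. Protocadherin clusters had too few tested fragments for a list test, and their named fragment, the promoter of Pcdhgc5, rose by 2.22.

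The remaining lists were not called by camera, while fry called imprinted genes as lower (fry adjusted p = 0.00585). Myogenic regulators had 16 fragments higher and 9 lower of 35 (the same adjusted over the list alone; camera adjusted p = 0.0962). Contractile genes had 16 and 22 of 69 (the same over the list alone), with Ryr1 up by 9.89 and the promoter of Cacng1, a calcium channel subunit of muscle, changed by -2.58. Germ line genes had 8 and 9 of 28, with Piwil1 up by 4.72 and Mov10l1, a helicase of germ line small RNAs, changed by -3.71. Imprinted genes had 8 and 16 of 37, with Phlda2 up by 4.28 at an island exon and an exon of Kcnq1, a potassium channel, changed by -3.56. Blood cell genes had 14 and 15 of 41, with Itgam at 155 ± 18.1 against 0.236 ± 0.274 CPM. Endothelial genes had 9 and 11 of 39, with Eng up by 3.94 and Flt1, a receptor of vascular growth factor, changed by -3.89. Fibroblast genes had 12 and 12 of 36, with an island intron of the mesenchymal factor Tbx15 up by 6.39. Adipocyte genes had 6 and 5 of 20, both directions being seen within Prdm16, a regulator of brown fat, at 2.16 and -3.01. Schwann cell genes had 2 and 0 of 7, with Erbb3, a neuregulin receptor, up by 4.21.

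The promoter island of Gtf2h1, a subunit of the general factor TFIIH (chromosome 7, 54051714 to 54051955), was at least 2230.5-fold higher in muscle (2530 against 0 reads), and an intron of Specc1 was at least 1199-fold lower (0 against 9857 reads). An intron of the aldehyde oxidase gene Aox4 rose by 9.79, and a 13652 bp fragment at Shisa4 had 1 read against 3918, lower by a ratio of 1631 with an exact 95% interval from 293 to 64453. The limit of long fragments given above holds for Shisa4. CpG islands held 630 of the 5616 higher fragments, or 11.2% against 3.98% of those tested (odds ratio 7.57), shores 745 (odds ratio 3.26), promoters 1250 (odds ratio 2.19) and LTR elements 681 (odds ratio 0.564). Fragments of 2000 bp or longer held 5045 of the 7959 lower ones (odds ratio 10.4), exons 1437 (odds ratio 1.66) and islands 129 (odds ratio 0.298). Without the low-count filter the odds ratios of promoters and long fragments turned to 0.855 and 0.814, and that of islands among higher fragments was 1.09. With library totals as the scaling, 3643 were higher and 11063 lower, and the median of all log2 changes moved from -0.34 to -1.17. Rbfox3 lost its call without any 1 of the 6 libraries (edgeR adjusted p from 0.0772 to 0.153), the Cdh1 exon fragment without muscle 1 (0.057), and Acta1 passed without muscle 3 (0.00891). Rbfox3 was also lost with DESeq2's size factors (0.0577), all groups in one fit (0.085), the 4 ESC libraries apart (0.0619) and no filter (0.243), and Flt1 and Prdm16 with all groups in one fit (0.0707 and 0.112).

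Among 22379 fragments tested in the comparisons of myoblasts and of muscle with ESC, 1447 were higher in both myoblasts and muscle and 1976 lower in both, where independent lists would share 370 and 1043. The fold changes had a covariance of 6.42 and a correlation across fragments of 0.793. Unchanged groups simulated against the same ESC libraries gave a covariance of 0.218 and a correlation of 0.493, and shared at most 1 call. They had at most 2 calls in any direction, so few shared calls were built in. That count cannot tell how far shared controls raise the overlap of long lists. Fragments are not independent replicates, and with 3 ESC lines the controls could not be split, so part of the excess may come from the shared controls. The ESC lines also differ in strain from the myoblasts and, at least in part, from the muscles. Strain differences may therefore enter the shared calls too, and the overlap cannot tell strain from cell type.

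Muscle and cultured myoblasts, the comparison of tissue with its precursors in culture, differed at 6309 of 20274 fragments with all libraries (2779 higher and 3530 lower in muscle), and at 0 without muscle 1 or muscle 2. The smallest edgeR adjusted p was then 0.0601 and 0.0587, with 7165 and 7725 fragments at an unadjusted p under 0.05, so each call of a single fragment that follows needs both of these libraries, which are of mixed background. The folds themselves stayed about as large, as for Myf5 (3.49 and 2.88 without muscle 1 and 2), Ckm (3.75 and 3.30) and Eno3 (6.81 and 7.08). With all groups in one fit, Myf5 (edgeR adjusted p = 0.099), Pax3 (0.0867), Pax7 (0.0544), Ckm (0.165) and Acta1 (0.126) lost their calls too. The Myf5 exon fragment was higher in muscle (40.2 ± 19.8 against 4.26 ± 3.12 CPM; 3.23 ± 0.81 on the log2 scale; edgeR adjusted p = 0.0195). The Pax3 promoter island stood at 147 ± 98.1 against 10.5 ± 9.66 CPM, higher by 3.80, and a 79 bp promoter island fragment of Pax7 was higher by 5.10. Ckm stood at 58.8 ± 14.6 against 5.43 ± 4.67 CPM, higher by 3.43, and Acta1 at 191 ± 136 against 30.4 ± 28.2, higher by 2.65. An 84 bp Dppa4 promoter fragment stood at 21.9 ± 10.4 against 1.78 ± 0.172 CPM, higher by 3.61. The 528 bp Dppa4 fragment had 408 to 696 CPM of all reads in the muscle libraries and 194 to 241 in the myoblast libraries. An exon of Ttn, the sarcomere protein titin, was lower in muscle at 115 ± 3.85 against 887 ± 555 CPM. The island promoter of Eno3, muscle enolase, had 133 reads against 1, a ratio of 179.6 with an exact 95% interval from 31.7 to 7145.

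**Figure D1:**
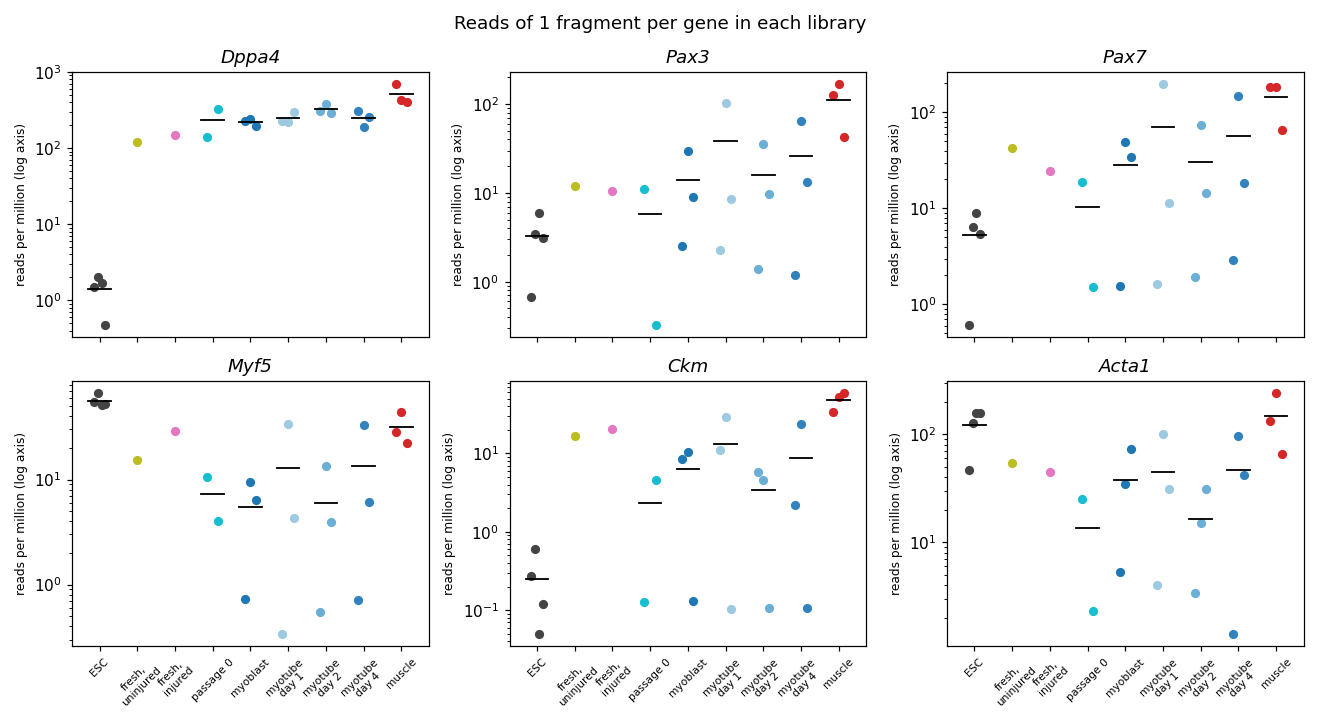
CPM of all reads (log axis) of 1 fragment each of Dppa4, Pax3, Pax7, Myf5, Ckm and Acta1 in every library by group. Points are libraries, lines are group means, and values under 0.05 are drawn at 0.05, as for Ckm in 1 ESC library; Dppa4 lies higher in every library of the other groups than in the 4 ESC libraries, and Myf5 lies lower in the 3 myoblast libraries than in ESC.

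HOX genes had 10 fragments higher and 0 lower of 17 in muscle (11 and 0 adjusted over the list alone; camera adjusted p = 0.00306, and 0.613 with an estimated correlation), with Hoxc10 up by 2.78. Neural genes had 12 and 2 of 46 (the same over the list alone; 0.00306, and 0.613 with an estimated correlation), with the promoter of the eye and pituitary factor Six6 up by 3.34 and an exon of Pax6 changed by -1.84. Adipocyte genes had 7 and 0 of 18 (8 and 0 over the list alone; 0.00421, and 0.613 with an estimated correlation), with an exon of Plin1 at 643 ± 349 against 50.2 ± 31.7 CPM. Endoderm genes had 7 and 0 of 23 (the same over the list alone; 0.0231, and 0.613 with an estimated correlation), with Prox1 up by 4.54. All of these list calls were also lost with fry (0.145 to 0.146), and that of endoderm genes outside islands (0.0727). They were kept without muscle 1 (0.00392, 0.000112, 0.00187 and 0.00494 in the order above) and without muscle 2 (0.00428, 0.00266, 0.00684 and 0.0195). The endoderm median, 0.50 with the main scaling, was -0.03 with library totals. Promoter island reads, given above for muscle, numbered 3165, 11150 and 8611 CPM in myoblast cultures 21, 27 and 26.

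Among lists without a call, pluripotency genes had 8 higher and 5 lower of 21, with Nr5a2 changed by -2.70. Myogenic regulators had 7 and 6 of 34 (11 and 7 adjusted over the list alone), and contractile genes 17 and 12 of 63. Germ line genes had 2 and 5 of 24, with Dmrtb1 up by 3.24 and Mov10l1 changed by -4.13. Imprinted genes had 7 and 7 of 31, with an intron of Kcnq1 up by 3.76 and Airn, a noncoding RNA of the Igf2r locus, changed by -2.54. Blood cell genes had 7 and 7 of 36, with an intron of Runx3 at 509 ± 127 against 76.0 ± 12.5 CPM and the promoter of Lck, a T cell kinase, changed by -3.02. Endothelial genes had 5 and 2 of 32, with Emcn up by 3.21 and Vwf, von Willebrand factor, changed by -1.67. Fibroblast genes had 5 and 2 of 38, with Tbx15 up by 5.16, and Schwann cell genes 3 and 0 of 7, with an exon of Mbp, myelin basic protein, up by 2.20. Pcdhgc5 rose by 1.95.

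**Figure D2:**
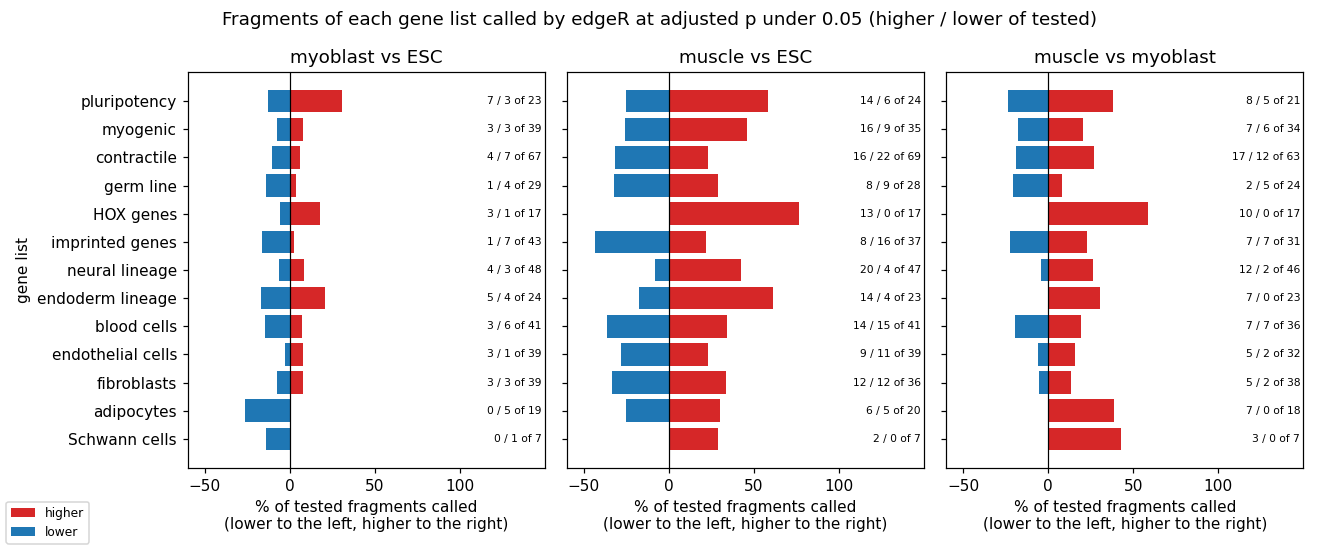
Share of tested fragments of each gene list (vertical axis) that edgeR called, in % of tested fragments, lower to the left in blue and higher to the right in red, with the counts higher / lower of tested at the right edge, for myoblasts against ESC, muscle against ESC and muscle against myoblasts. HOX genes show 13 and 10 of 17 fragments higher in muscle in the comparisons with ESC and with myoblasts, and 0 lower in both.

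Outside the lists, the largest folds under the rule for named genes were at the promoter of Lypd3, up by 6.61 in muscle, and at the 80375 bp fragment of Fbxo33, with 7 reads against 11643. The limit of long fragments given above holds for Fbxo33. Among the smallest adjusted p values were those of an intron of the hormone receptor gene Pth2r, up by 3.09, and of an exon of Cspp1, changed by -4.14 (edgeR adjusted p = 0.012 for both). Islands held 251 of the higher fragments (odds ratio 2.86) and 14 of the lower ones (odds ratio 0.0770), shores 374 of the higher (odds ratio 2.57), promoters 575 (odds ratio 1.83), and LINE elements 210 (odds ratio 0.375). Without the low-count filter the ratio of promoters turned to 0.928 and that of islands among higher fragments was 1.18. SINE elements held 786 of the lower fragments (odds ratio 1.80) and exons 702 (odds ratio 1.86). Total calls fell to 3497 without culture 27 and to 3195 without culture 26. With library totals as the scaling 1283 were higher and 4183 lower and the median moved from -0.13 to -0.67, and with all groups in one fit 1325 were higher and 3609 lower. With all groups in one fit, 11 of the 29 named calls were lost (edgeR adjusted p from 0.051 to 0.165). Library totals ended 5 (Myf5, Ckm, Acta1, Hoxc10 and Pcdhgc5; 0.0501 to 0.1), the lack of a filter Nr5a2, Pax6 and Vwf (0.0529 to 0.281), and fragments under 2000 bp alone Acta1 and Pcdhgc5 (0.0618 and 0.0674). All 29 were lost without muscle 1 (edgeR adjusted p from 0.0601 to 0.232) or muscle 2 (0.0587 to 0.153), with folds of the same sign, as for Fbxo33 (-11.34 and -9.72), and 3 without muscle 3 (Pcdhgc5, Pax6 and Vwf; 0.0514 to 0.0726). Calls were lost for 6 without culture 27 (Ckm, Acta1, Pcdhgc5, Vwf, Tbx15 and Mbp; 0.0537 to 0.138) and for 8 without culture 26 (Myf5, Pax3, Dmrtb1, Hoxc10, Pcdhgc5, Six6, Pax6 and Vwf; 0.0504 to 0.0773).

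Between muscle and day 4 myotubes, none of the named muscle genes passed in edgeR, though each had a higher mean in muscle. Ckm stood at 54.4 ± 13.3 CPM in muscle and 6.68 ± 9.04 in myotubes, and Pax3 at 136 ± 90.1 and 19.2 ± 23.1 (edgeR adjusted p = 0.196 and 0.184). Myf5 stood at 37.1 ± 18.1 and 9.86 ± 12.1, and Acta1 at 177 ± 125 and 34.9 ± 33.4 (0.278 and 0.229). The 84 bp Dppa4 and 79 bp Pax7 promoter fragments differed by 2.94 and 3.61 (edgeR adjusted p = 0.138 and 0.146). Neural and HOX genes were higher as groups in muscle (camera adjusted p = 0.00713 and 0.0358), and neither was with an estimated correlation (camera adjusted p = 0.63 with an estimated correlation for both) or without day 4 library 1 (0.0771 and 0.12). Fry called neither (0.403 and 0.382), and HOX genes were lost outside islands (0.129) and with library totals (0.0508). Adjusted over the list alone, imprinted genes had 3 fragments higher and 5 lower and germ line genes 0 and 1. The edgeR test called 0 of 19353 fragments, with 4613 at an unadjusted p under 0.05. DESeq2 called 761 higher and 1470 lower, edgeR with all groups in one fit called 463 and 2098, and edgeR without day 4 library 1 called 523 and 1867. Dppa4 and Pax7 passed without that library (edgeR adjusted p = 0.0213 and 0.0476). With DESeq2, Dppa4, Pax3, Pax7 and Ckm passed (adjusted p = 0.0119, 0.0376, 0.00995 and 0.0402), as did Dppa4 with all groups in one fit (edgeR adjusted p = 0.013).

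Differentiation in culture was followed at 1, 2 and 4 days against the myoblasts of the same cultures, and no named muscle gene passed at any day. Myf5 stood at 4.64 ± 3.26 CPM in myoblasts and 14.1 ± 20.3 at day 1, and Pax3 at 11.2 ± 9.56 and 41.8 ± 62.5. At day 2, Ckm stood at 5.99 ± 5.09 in myoblasts and 4.07 ± 3.45 in myotubes, and Myf5 at 4.99 ± 3.70 and 7.24 ± 9.15. At day 4, a promoter island fragment of Pax3 stood at 1.64 ± 1.01 and 3.24 ± 4.24 CPM, Ckm at 5.93 ± 5.21 and 7.95 ± 10.6, and an island exon fragment of Pax7 at 0.893 ± 0.827 and 4.91 ± 6.01. The 84 bp Dppa4 fragment differed by 0.68 at day 1 and 0.70 at day 4 and the 528 bp Dppa4 fragment by 0.76 at day 2, and Tdgf1, a co-receptor of Nodal signals in pluripotent cells, by -0.37, -0.16 and -0.73. Culture 27 carried the high values. At day 1 without its myotube library the log2 changes of Myf5 and Pax3 went from 1.60 and 1.89 to -0.95 and -0.97. Those of Acta1 and a 219 bp Pax7 fragment went from 0.53 and 1.98 to -0.89 and -0.99.

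Adipocyte, HOX, endoderm and neural genes were higher as groups at day 1 (camera adjusted p = 0.0023, 0.00574, 0.00574 and 0.0075). None was with an estimated correlation (camera adjusted p = 0.495 with an estimated correlation for the first 3 and 0.539 for neural genes) or with fry (0.809 for each), nor neural genes outside islands (0.0817). Without the day 1 library of culture 27 all were lower as groups and lost their call (0.128, 0.0521, 0.205 and 0.0521). Without the myoblast library of culture 21 the calls were lost too (0.581, 0.301, 0.301 and 0.963), as were those of neural genes without that of culture 27 (0.0839) and of endoderm genes without that of culture 26 (0.0952). The day 1 library of culture 27 had 37143 CPM in promoter islands and the day 4 library of the same culture 34472, against 12131 at day 2 and 11150 as myoblasts, while libraries of cultures 21 and 26 had 2862 to 8611. No list was called at day 2 or day 4 (lowest camera adjusted p = 0.0689 and 0.0859). For single fragments, edgeR called 0 of 22016 at day 1, 0 of 21781 at day 2 and 0 of 22438 at day 4, with 6, 64 and 83 at an unadjusted p under 0.05. These are 0.027%, 0.29% and 0.37% of the fragments, far below the share that a threshold of 0.05 gives with no change. This fit leaves out the pairing by culture, and its 0 calls do not show that nothing changed. DESeq2 called 0 at each day. With the culture as a block edgeR called 0 at days 1 and 2 and 39 at day 4, all higher in myotubes. The shares at an unadjusted p under 0.05 were then 0.31%, 3.5% and 4.7%. In data simulated with the spread of the day 4 comparison and no pairing by culture, 0 of 100 fragments changed 16-fold were recovered.

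**Figure D3:**
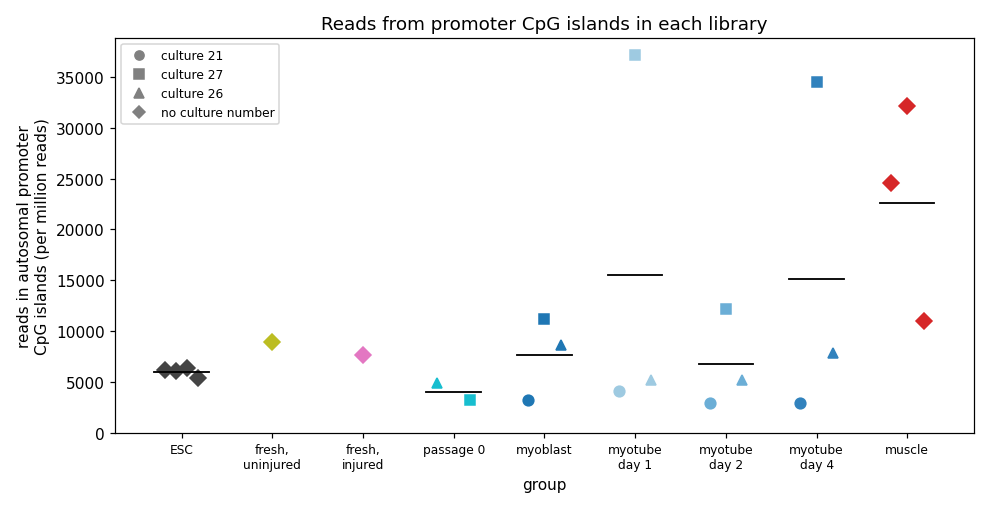
Reads from autosomal promoter CpG islands (CPM, vertical axis) in each library by group (horizontal axis), with a marker per culture and lines for group means. The day 1 and day 4 libraries of culture 27, at 37143 and 34472 CPM, and muscle libraries 1 and 2 lie above all other libraries.

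Growth in culture from passage 0 to passage 8 to 10 was compared between the 3 myoblast and 2 passage 0 libraries. A promoter island fragment of Pax3 (chromosome 1, 78191818 to 78193207) had 50 reads against 2, a ratio of 12.5 with an exact 95% interval from 3.28 to 106, and did not pass (edgeR adjusted p = 0.978). A 2582 bp Pax7 fragment differed by 1.97, Acta1 by 1.36 and Ckm by 0.98. Myf5 differed by -0.72, the 84 bp Dppa4 fragment by -0.59 and Tdgf1 by -0.14, and none of these 6 fragments passed. The value of Ckm depends on the cultures in each group. Culture 26 had 1 Ckm read at either passage, and the change ranged from -0.031 to 5.47 with a library left out. Myogenic regulators (camera adjusted p = 0.000868) and HOX, neural and fibroblast genes (0.0116 each) were higher as groups in the later passage, and none was with an estimated correlation (camera adjusted p = 0.527 with an estimated correlation, 0.62 for neural genes) or with fry (0.537, and 0.606 for neural genes). Outside islands the HOX, neural and fibroblast calls were lost (0.0856, 0.131 and 0.0856). Without culture 27 at the later passage the myogenic, HOX and neural calls were lost (0.0676, 0.168 and 0.229), and without culture 26 all 4 (0.0564, 0.166, 0.496 and 0.232). Without culture 27 at passage 0 the HOX, neural and fibroblast calls were lost (0.354, 0.567 and 0.0638), and that of fibroblast genes also without culture 21 (0.0554), without culture 26 at passage 0 (0.0772) and with the block (0.0801). Promoter island reads were 4853 and 3187 CPM in the passage 0 libraries of cultures 26 and 27. The edgeR test called 0 of 23419 fragments with 665 at an unadjusted p under 0.05. DESeq2 called 3, all of them long and higher in myoblasts, at Snx7 (9.32), 2810474O19Rik (13.69) and Fbxo33 (11.11), which are named after their values were seen. With the culture as a block, which uses cultures 26 and 27 alone and leaves 1 residual degree of freedom, edgeR called 878 higher and 156 lower, among them Pax3 at 4.07 (adjusted p = 0.0332) and Acta1 at 2.27 (adjusted p = 0.0161). Adipocyte genes were then called as higher (camera adjusted p = 0.0154, main 0.155). On the same 22202 fragments of these cultures without the block, it called 0, with 2414 at an unadjusted p under 0.05.

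The authors' deposited tables cover 7 of these 9 comparisons, for fragments under 2000 bp. In the authors' deposited table of muscle against ESC, 3919 fragments were higher and 6523 lower at an adjusted p under 0.05 with pooled dispersion, and 6208 of the 8247 fragments called here and present there were called with the same sign. For muscle against myoblasts the authors' deposited table has 2791 higher and 4002 lower, with 3976 of 4402 shared, and for myoblasts against ESC it has 2593 and 3267, with 2801 of 3063 shared. The authors' deposited table of day 4 myotubes against ESC has 1629 and 3084, with 1183 of 1307 shared. With per condition dispersion the authors' deposited tables have 4548 higher and 8429 lower for muscle against ESC, 3200 and 5976 for muscle against myoblasts, 3865 and 4069 for myoblasts against ESC, and 4380 and 3500 for day 4 myotubes against ESC. In the authors' deposited tables, muscle against day 4 myotubes has 1043 and 1892 with pooled and 1775 and 6413 with per condition dispersion. Myoblasts against passage 0 have 142 and 263, and 1463 and 930, and day 4 myotubes against myoblasts have 3 and 5, and 537 and 247, in the same order. Among fragments called both here and in the authors' deposited tables, none had the opposite sign. For calls made here alone the signs were not compared.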

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

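Fragments under 2000 bp, autosomes, fragments outside CpG islands and the second CGR8 library alone were chosen after the data were seen, and all other alternatives were set in advance. Under alternatives other than a left-out library, 66 counts of calls stayed within 1.5 times the main count and 16 moved. Of the values of named fragments, 1198 kept direction and side of the threshold, 49 lost their call, 12 gained one and 6 turned direction. With a library left out these numbers were 674, 128, 7 and 21, and 46 counts stayed while 7 moved. List calls stayed in 80 cases and were lost in 48, and with a library left out stayed in 83, were lost in 28 and turned in 5. Of 117 list tests, 20 were called with the main setting, 0 with an estimated correlation, 20 with DESeq2's size factors (18 shared), 24 with library totals (19 shared), 14 outside islands (13 shared) and 20 on autosomes (20 shared). Lists called there alone include myogenic regulators in muscle against ESC with library totals (camera adjusted p = 0.0453, main 0.0962) and adipocyte genes in muscle against day 4 myotubes outside islands (0.0187, main 0.052). Numbers of detected fragments kept their direction in all 12 alternatives and overlaps in all 4. Of 100 simulated 4-fold changes between muscle and myoblasts, 2 were recovered. That simulation changed far fewer fragments than the 6309 called here, so its adjusted threshold was stricter. Power in the real comparison was therefore not measured, nor was the part that depth has in it. Unless a cause is given, the cause was not tested.

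With fragments under 2000 bp alone, fewer fragments were tested and calls numbered 2632 for myoblasts against ESC (main 5005), 1075 for day 4 myotubes against ESC (main 2893), 8255 for muscle against ESC (main 13575) and 4042 for muscle against myoblasts (main 6309). Without a low-count filter they numbered 6173 for day 4 myotubes against ESC, 522 for muscle against day 4 myotubes (main 0), 31, 4 and 107 for days 1, 2 and 4 against myoblasts (main 0 each) and 51 for myoblasts against passage 0 (main 0). The 4 of day 2, named after their values were seen, were long and lower in myotubes, at Gimap7 and Gimap1 (-6.38), at Tle3 (-5.09) and at 2 fragments without a gene (-5.38 and -5.93). With DESeq2, calls numbered 4592 for day 4 myotubes against ESC, 2231 for muscle against day 4 myotubes and 3 for myoblasts against passage 0, at Snx7, 2810474O19Rik and Fbxo33. With all groups in one fit there were 2561 for muscle against day 4 myotubes.

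With the culture as a replicate block, calls numbered 39 for day 4 myotubes against myoblasts and 1034 for myoblasts against passage 0 (main 0 for both). The latter fit uses cultures 26 and 27 alone, which gave 0 calls without the block. Acta1 at day 4 went from 0.27 to -0.16 on the log2 scale with the block. The fibroblast list against passage 0 lost its call (camera adjusted p = 0.0801) and the adipocyte list gained one (0.0154, main 0.155), as did Pax3 and Acta1 there, and the block changed no other call of a list or named fragment.

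Of 75 contexts past the threshold, 8 turned with DESeq2 and 21 without the filter, where the background grows by construction to as many as 144480 fragments. Among those in the text, the odds ratio of islands among higher fragments in day 4 myotubes against ESC went from 0.441 to 5.83 with DESeq2 and to 2.03 without the filter. Without the filter that of LINE elements there went from 1.60 to 0.827, and that of fragments of 2000 bp or longer among lower ones from 2.31 to 0.354 for myoblasts and from 10.4 to 0.814 for muscle against ESC. Promoters among higher fragments went from 2.19 to 0.855 for muscle against ESC and from 1.83 to 0.928 for muscle against myoblasts. As a share of detected fragments instead of reads, the island difference of myoblasts minus ESC went from 0.309 to -0.315 percentage points.

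The log2 change of Myf5 in muscle against ESC went from 0.06 to -0.81 with library totals, -0.039 without the filter and -0.40 under 2000 bp. That of Tdgf1 went from -0.16 to 0.033 at day 2 without the filter, and from -0.14 to 0.15 against passage 0 with library totals. None of these passed in either setting.

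With each library left out in turn, calls ranged from 3247 to 7421 for myoblasts against ESC, 2040 to 6146 for day 4 myotubes against ESC, 0 to 8107 for muscle against myoblasts and 0 to 2390 for muscle against day 4 myotubes. Camera adjusted p at day 1 ranged from 6.9e-05 to 0.301 for HOX, 1.9e-05 to 0.963 for neural, 0.000686 to 0.301 for endoderm and 6.9e-05 to 0.581 for adipocyte genes. These lists turned lower without the day 1 library of culture 27, and neural genes also without culture 21 as myoblasts. Myf5 in muscle against ESC ranged from -0.23 to 0.44. At day 1 the ranges of log2 changes were -1.16 to 0.075 for Tdgf1, -0.95 to 2.15 for Myf5, -0.97 to 2.83 for Pax3, -0.99 to 2.64 for Pax7 and -0.89 to 1.68 for Acta1. At day 2 they were -0.41 to 0.40 for Tdgf1, -1.10 to 1.27 for Myf5, -1.06 to 1.71 for Pax3 and -1.11 to 0.29 for Ckm. At day 4 they were -0.025 to 1.02 for Dppa4, -0.39 to 1.84 for Myf5, -1.001 to 1.49 for Pax3, -1.64 to 1.04 for Ckm and -0.69 to 1.38 for Acta1. Against passage 0 they were -0.41 to 0.13 for Tdgf1 and -0.031 to 5.47 for Ckm.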

Other observations

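Muscle precursor cells that were never cultured were sequenced once from uninjured muscle and once from muscle 3 days after injury, so their values have no test. Over 23701 fragments, the library from uninjured muscle had a Spearman correlation of 0.939 with the myoblast mean, 0.919 with passage 0, 0.849 with muscle, 0.648 with ESC and 0.957 with the library from injured muscle. The library from injured muscle stood at 0.945, 0.925, 0.848 and 0.685 with the same groups. The Dppa4 promoter had 121 CPM (95% counting interval 113 to 130) in cells from uninjured and 147 (139 to 156) in cells from injured muscle, with a myoblast mean of 221. The Myf5 exon fragment had 15.2 (12.3 to 18.6) and 29.3 (25.6 to 33.4), with a myoblast mean of 5.50. The 522 bp Pax7 exon fragment stood at 74.4 and 43.7, Pax3 at 11.9 and 10.5, and Acta1 at 54.0 and 44.4 CPM.

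By gene list, the median log2 difference of injured minus uninjured was -0.12 for neural genes, at percentile 0.07 of 10000 random lists of as many fragments, and -0.16 for HOX genes, at percentile 2.19. Contractile genes stood at 0.44 (percentile 98.6) and germ line genes at 0.44 (percentile 96.9). Against the myoblast mean, myogenic regulators stood at -0.34 in cells from uninjured muscle (percentile 0.23) and at -0.19 in cells from injured muscle (percentile 0.02). Adipocyte genes stood at 0.44 (percentile 98) and 0.74 (percentile 99.8), and germ line genes at -0.37 (percentile 1) and 0.15 (percentile 57.8). These percentiles place a list among fragments of the same libraries and are not tests between cells. The random lists were matched on size and mean level but not on CpG islands. Promoter island reads were 8956 CPM in the library from uninjured and 7668 in that from injured muscle, so the island level may enter the percentiles.

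The tests of culture 26, of CpG islands with and without a matched partner apart, of fragments of 2000 bp or longer absent in myoblasts and of the sample splits were chosen after the results were seen, and the other tests of CpG islands and those of fragments absent in ESC before.

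CpG islands had more reads in muscle than in ESC. Less complete SmaI digestion in muscle stays open: promoter islands of housekeeping genes stood 2.34 higher in muscle on the log2 scale against 1.88 at other promoter islands, a ratio of 1.24 (1.202 to 1.287 without 1 muscle library). PCR favouring GC-rich fragments is argued against for the 4289 of 7508 island fragments with a partner of the same GC and length outside islands, which stood 2.89 higher in muscle against -0.09 at their partners, a ratio of -0.0299 (-0.0656 to -0.0129 without 1 muscle library), and which held 99.7% to 99.9% of the muscle reads of these islands. Matching reached 57.1% of fragments, under the 80% needed, so the test is void for all islands together. The other 3219 (median GC 72.2%) were not higher in muscle (-1.74, and -0.28 without the 1 fragment with most reads). They held only the small rest of the muscle reads and 1 fragment moved their value, so they cannot decide on PCR there. Methylation gained at developmental gene islands also has the value it needs, a log2 ratio of 3.47 there, which is 1.14 above housekeeping islands (1.00 to 1.23 without 1 muscle library).

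The libraries of culture 26 differ from those of cultures 21 and 27 on the sex chromosomes although all are labelled male. GC or length bias is argued against, since autosomal fragments of the same GC and length stood at 0.961 of cultures 21 and 27 (0.921 to 0.999 by library). A female source stays open. X reads outside islands were 22985 ± 2639 CPM (n = 5 libraries, all of culture 26) against 12815 ± 1251 (n = 9 libraries of cultures 21 and 27), a ratio of 1.79. The SD covers repeat libraries of the same cultures and not independent sources. Y levels, however, were 75.9% at 20 Y gene fragments, 29.2% at 4 Y fragments without a near copy and 5.80% at 34 Y fragments under 2000 bp. The first rule, Y over 25% or X under 1.2 times, would have excluded a female source from the first 2 sets; after their values were seen the third set was added and the rule changed to over 25% in each set, because long Y fragments are hardly amplified and their reads might come from near copies, which was not established. Under either rule a female source is not shown. Muscle 2 and the never cultured cells, with 20048, 30089 and 26926 CPM on X and 2.79, 10.1 and 13.7 on short Y fragments, had values like those of culture 26. The 20 Y gene fragments did not separate muscle 2 (32.1 CPM) from muscle 1 (29.9), though short Y fragments did (2.79 and 91.2). That set may therefore be unable to decide. Short Y reads were 5.78 to 8.98 CPM in culture 26 and 74.1 to 146 in cultures 21 and 27. X island reads averaged 292% of those of cultures 21 and 27, with overlapping ranges (292 to 493 and 34.0 to 384 CPM).

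Some fragments called between myoblasts and ESC had almost no reads in one of them. Of 2068 higher in myoblasts, 361 had under 3 reads in each ESC line. At the myoblast level the smallest ESC library would hold a median of 50.6 of their reads (34.1 to 66.7 by culture), more than lower ESC depth allows. A call from so few ESC reads needs many myoblast reads, so a high value was largely built in and is weak evidence against depth. The library totals say more. ESC lines held 24505365, 10083435 and 8374971 reads, and myoblast libraries 11041705, 9673946 and 7683633. As a group the ESC lines were thus not sequenced less, which argues against lower ESC depth for these fragments. Sites lost in the 129 background stay open for these, with 5.52% of 145 usable fragments low in a mixed muscle against 3.36% of uncalled ones, a ratio of 1.64 (bootstrap 95% interval 0.616 to 2.87). Of 1587 fragments of 2000 bp or longer lower in myoblasts, 709 were absent there, and larger ESC inserts are argued against, since 58.1% of their ESC reads lie in fragments of 10000 bp or longer. Extra 129 sites that shorten these were first read as excluded, as mixed muscles had 0.862 of the reads of the C57BL/6J muscle, and were reopened after that value was seen because no label gives the 129 share of those muscles; strain and cell type cannot be told apart here.

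For the counts of calls, each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split gave 5005 calls for myoblasts, 2893 for day 4 myotubes and 13575 for muscle against ESC and 6309 for muscle against myoblasts, where the highest other split gave 0, so 1 of 10 was as large. For muscle against day 4 myotubes the real split gave 0 and the highest other 24, and for days 1, 2 and 4 against myoblasts all gave 0. A real count of 0 makes 10 of 10 splits as large by construction, so these splits decide nothing. Those of days 1, 2 and 4 also leave out the pairing by culture.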
